A study of Homo sapiens with 21 samples.

How the data were processed

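PolyA RNA was measured in 21 libraries of 3 human pluripotent stem cell lines. Per the labels' protocols, RNA was extracted with Trizol and cleaned on columns, and GeneWiz enriched and fragmented mRNA, made cDNA from random primers and sequenced the libraries. Groups were taken from the sample titles and cell line labels: undifferentiated stem cells and weeks 4, 6, 7 and 8 of the H9-LHX6-GFP line, and HES3-NKX2.1-GFP and WTSIi015-A at a titled week 7, with 3 libraries each. The labels assign the first of these lines to batch 1 and the others to batch 2.

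The deposited values are TPM, length-scaled transcript abundances computed by the authors from reads before deposit, on hg38 per the submitters' processing notes. The aligner, counting tool, annotation and gene filter are not given in the sources used here. TPM divides by gene length and scales each library to a fixed sum, so a large change in a few abundant genes, such as the mitochondrially encoded ones, shifts the values of all others, and read depth is lost, so that no counting error can be given. The 19580 listed genes summed to between 988082 and 993030 TPM per library, so a small part of each library lies outside the list. Ensembl IDs of 19449 genes matched GENCODE release 29, whose coordinates are printed, and 131 did not match. Of the symbols 23 had turned into dates and 100 were missing, and these were replaced through the Ensembl ID. No pair of libraries had identical values, and 0 columns were left unmapped to a sample. Without knowledge of strand or of how shared reads were counted, pseudogenes, small RNA genes and overlapping genes are uncertain.

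Values were transformed to log2(TPM + 1), with a pseudocount of 1, and genes with a TPM of 1 or more in at least 3 libraries of a fit were tested with limma 3.58.1 (trend and robust empirical Bayes) in R 4.3.3. The 5 comparisons over time came from 1 fit of the 15 LHX6 line libraries, and the 3 comparisons between lines from 1 fit of the 9 libraries titled week 7. P-values were two-sided and adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. Tables were handled with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots drawn with matplotlib 3.10.9.

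Before the data were examined, 26 gene lists were fixed. They cover pluripotency, ventral telencephalic progenitor factors, MGE-derived interneuron precursors, GABA synthesis and release, interneuron subtype peptides and calcium-binding proteins, tangential migration and guidance, receptors for glioma-secreted factors, matrix proteases with inhibitors and integrins, early neurons, synapse and excitability, and the cell cycle. Lists for other cell types and states cover radial glia, astrocytes, the oligodendrocyte lineage, cortical glutamatergic neurons, CGE and LGE interneurons, cholinergic and striatal projection neurons, diencephalon to hindbrain, choroid plexus and ependyma, mesenchyme and pericytes, endothelium and microglia, endoderm and epithelium, SHH and WNT readouts, hypoxia and glycolysis, stress and immediate early genes, and mitochondrially encoded genes. MGE, CGE and LGE are the medial, caudal and lateral ganglionic eminence. Each list was tested against all other genes with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, each adjusted over the 26 lists within a comparison.

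Genes named in the text follow a rule set before the data were examined. It takes the 5 largest rises and 5 largest falls per comparison (3 each for adjacent weeks) among genes past the threshold, with a mean of 5 TPM or more in the higher group and no overlap between groups, skipping unnamed loci. It adds 16 key genes and up to 4 members of each list with the smallest adjusted p, other members being given only as values. CHCHD2 in the account of week 4 was singled out after its values were seen.

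The test was tried on simulated data with the real genes' means and spreads and 200 changed genes, at log2 changes of 0.5, 1 and 2. The changed genes were drawn only from the more highly expressed ones, so recovery among low genes was not tried. They were a small part of all genes, whereas 83.3% were called in the real comparison of week 4 with stem cells. The false shares therefore need not carry over to the real data. For week 4 against stem cells it recovered 94.0%, 98.5% and 100% of them, with 8.02% of calls false, over 18898 genes. For week 8 against week 7 the shares were 89.6%, 100% and 98.5% with 9.01% false over 18929 genes, and for the WT15 against the NKX2.1 line 80.6%, 97.0% and 98.5% with 7.54% false over 18677 genes. Over all 8 comparisons the false share was 4.48% for week 6 against week 4 and 4.46% for week 7 against week 6, and lay between 5.56% and 9.01% for the others, above the nominal 5%.

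The alternatives fixed beforehand were a pseudocount of 0.1, no filter on low values, median-of-ratios scaling, quantile normalization, a fit of only the compared groups, a fit of all 21 libraries, the replicate number as a block, a test against a log2 change of 1 (treat), and leaving out each replicate. Chosen after seeing the data were leaving out mitochondrial genes with rescaling, protein-coding genes only, and week 6 or week 8 in place of week 4 or fits without week 4. Genes set apart in a group of the LHX6 line (over 8-fold on the log2(TPM + 1) scale from every other group of the line) and chromosome medians (protein-coding autosomal genes of 5 TPM or more in every group mean, each chromosome split at its middle gene) were looked at only after the data were examined. Levels of XIST and of Y-linked genes, and of some other genes that the rule would name, are not reported here.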

Results

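The data set holds polyA RNA sequencing of 21 libraries from human pluripotent stem cell lines taken through a differentiation towards migratory interneuron precursors, the young inhibitory neurons that leave the ventral forebrain. Each of 7 groups has 3 libraries. The reporter line H9-LHX6-GFP, called the LHX6 line here, was sampled as undifferentiated stem cells and after 4, 6, 7 and 8 weeks. The lines HES3-NKX2.1-GFP (the NKX2.1 line) and WTSIi015-A (the WT15 line) were each sampled once, and the sample titles place both at week 7. The library names of the WT15 line carry week 12 instead, so its time in culture is uncertain, and the text calls these libraries by their title. All LHX6 line libraries belong to batch 1 and those of the other lines to batch 2, so a difference between the LHX6 line and another line cannot be told apart from a difference between batches. Nothing in the labels says that the 3 libraries of a group were separate cultures, and p-values then measure only the spread between these libraries, which may be technical. Each week would then be a single culture, and a change between weeks could not be told apart from a difference between differentiation runs.

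Values are in TPM, transcript abundances scaled to a fixed sum per library, for 19580 genes, given as mean ± SD over n = 3 libraries. List members counted neither as risen nor as fallen did not pass the test. The unit keeps no read depth, so the depth of each library is unknown. Pearson correlations of log2(TPM + 1) across genes, which are not independent replicates, lay between 0.973 and 0.990 within groups. The first principal component held 53.3% of the variance and the second 15.7%. Mitochondrially encoded genes took 35.9% to 36.7% of TPM in stem cells, against 16.9% to 17.3% at week 4 and 11.2% to 13.2% in the libraries of batch 2. Log2 changes below are on the log2(TPM + 1) scale, which understates the change of low genes. On that scale the median gene lay 0.55 higher at week 4 than in stem cells, 0.18 higher in the NKX2.1 line and 0.12 higher in the WT15 line than in the LHX6 line at week 7, and changes of gene lists are given relative to the median of all genes. Changes and adjusted p-values come from limma with Benjamini-Hochberg adjustment, and list tests from its camera function with adjustment over the 26 lists. Coordinates are hg38.

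**Figure D1:**
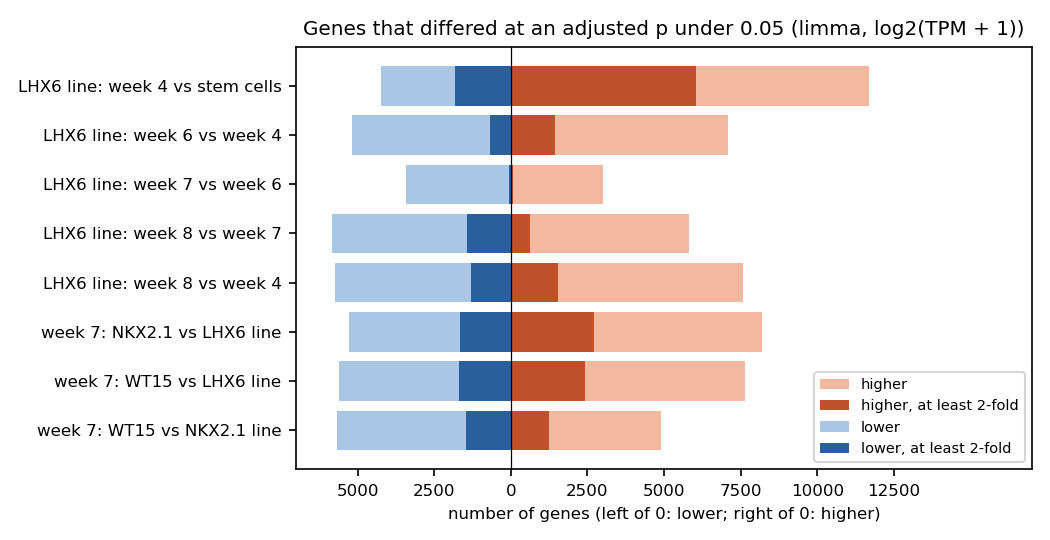
Number of genes higher (bars to the right of 0) and lower (bars to the left) in each of the 8 comparisons, at an adjusted p under 0.05; darker bars count genes that changed at least 2-fold. Week 7 against week 6 has the shortest bars, with 3002 genes higher and 3427 lower.

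The week 4 libraries labelled as the LHX6 line had little of pluripotency transcripts and carried those of the ventral forebrain. They may hold cells of another line or clone, as described under the other observations, and this doubt applies to every comparison with week 4. The pluripotency call held with an estimated correlation and that of ventral telencephalic factors did not (adjusted p = 0.0384 and 0.091). POU5F1 (ENSG00000204531, chromosome 6, 31164337 to 31180731), the core pluripotency factor, dropped from 1403 ± 17.2 TPM in stem cells to 1.91 ± 2.66 at week 4 (log2 change -9.29 ± 0.66 (SE), adjusted p = 1.12e-08), and NANOG (ENSG00000111704, chromosome 12, 7787794 to 7799141) was at 17.8 ± 0.601 TPM in stem cells and listed at 0 in each week 4 library. Of 17 measured pluripotency genes 17 fell (list median -4.78 relative to all genes), TDGF1 by a log2 change of -6.66 and ZFP42 by -6.54. NKX2-1 (ENSG00000136352, chromosome 14, 36516392 to 36521149), which specifies the medial ganglionic eminence, rose from 0.977 ± 0.264 to 339 ± 13.7 TPM (log2 change 7.43 ± 0.073 (SE), adjusted p = 1.39e-17). Of 15 ventral telencephalic progenitor factors 15 rose (list median 4.95), among them DLL1 (5.38) and GSX2 (from 0.515 ± 0.0641 to 103 ± 2.38 TPM). Of 13 early neuron genes 13 rose (list median 3.43), including TUBB3 (4.39) and ELAVL3 (5.76).

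Genes of GABA synthesis and release rose in 5 of 5 cases: GAD1 (ENSG00000128683, chromosome 2, 170813213 to 170861151) went from 4.73 ± 0.0746 to 57.4 ± 1.63 TPM and GAD2 (ENSG00000136750, chromosome 10, 26216307 to 26304558) from 2.30 ± 0.216 to 63.2 ± 2.07. LHX6 (ENSG00000106852, chromosome 9, 122202577 to 122229626), the factor of migrating interneurons of the medial ganglionic eminence, rose to 56.0 ± 0.404 TPM and LHX8 (ENSG00000162624, chromosome 1, 75128434 to 75161533) to 73.4 ± 2.18. The distal-less genes DLX2 (ENSG00000115844, chromosome 2, 172099439 to 172102900) and DLX5 (ENSG00000105880, chromosome 7, 97020392 to 97024950) reached 241 ± 10.2 and 224 ± 1.69, and the neuropeptide gene SST (ENSG00000157005, chromosome 3, 187668906 to 187670399) reached 66.3 ± 2.18. Of 16 MGE-derived interneuron precursor genes 12 rose and 4 fell. Of 21 tangential migration and guidance genes 16 rose and 3 fell, among the former the chemokine receptors CXCR4 (ENSG00000121966, chromosome 2, 136114349 to 136118165, 3.74) and ACKR3 (ENSG00000144476, chromosome 2, 236567787 to 236582358, 3.52) and the neuronal microtubule gene DCX (ENSG00000077279, chromosome X, 111293779 to 111412429, 5.77). ERBB4 (ENSG00000178568, chromosome 2, 211375717 to 212538841), a receptor of migrating interneurons, was at 1.06 ± 0.0463 TPM in stem cells and 1.61 ± 0.245 at week 4. Radial glia genes rose in 10 of 13 cases (2 fell), with NES at 3.22. Of 26 synapse and excitability genes 18 rose and 6 fell. Among the genes that the naming rule takes for size, the largest rises included those of the Notch target HES5 (7.54), NKX2-1, NR2E1 (7.09) and MIR124-2 (6.99), whose short transcript is uncertain in such a library. After POU5F1 the largest falls were those of BST2 (-8.13), L1TD1 (-7.88), CLDN6 (-7.13) and ESRG (-6.96).

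Falls outside the pluripotency genes covered 6 of 6 endoderm and epithelium genes, such as CDH1 (-5.60), 10 of 13 (2 rose) mesenchyme and pericyte genes, 13 of 14 (1 rose) hypoxia and glycolysis genes, such as LDHA (-3.47), and 10 of 14 (4 rose) stress and immediate early genes. Of 10 astrocyte genes 7 fell and 2 rose (camera adjusted p = 0.0707 with quantile normalization), of 27 matrix proteases, inhibitors and integrins 15 fell and 9 rose (21 and 5 with median-of-ratios scaling, 20 and 5 with quantile normalization), and of 4 measured endothelium and microglia genes 3 fell and 1 rose. Mitochondrially encoded genes fell in 9 of 11 cases (2 rose), but with quantile normalization 5 rose and 5 fell (camera adjusted p = 0.937). Of 22 cell cycle genes 19 rose and 2 fell (list median 0.14), against 11 and 9 with median-of-ratios scaling and 14 and 7 with quantile normalization, under which the camera call was lost (adjusted p = 0.169). The gene MKI67 (ENSG00000148773, chromosome 10, 128096659 to 128126385) was at 68.8 ± 1.74 TPM in stem cells and 206 ± 4.45 at week 4. With week 6 in place of week 4 the balance of several lists turned. Of the cell cycle genes 7 rose and 12 fell, a fall called by both forms of camera (adjusted p = 0.00429, and 0.0492 with an estimated correlation). In the same comparison 8 astrocyte genes rose and 2 fell (camera adjusted p = 0.481), and 7 mesenchyme genes rose and 6 fell (0.373, with camera still giving a fall). With week 8 in its place 13 cell cycle genes rose and 7 fell (camera adjusted p = 0.687), 7 astrocyte genes rose and 3 fell (0.921), and 4 mesenchyme genes rose and 9 fell (0.00359, and 0.113 with an estimated correlation). In limma's camera test with a preset correlation, the adjusted p was 1.57e-12 for pluripotency, 5.71e-06 for ventral telencephalic factors, 1.18e-05 for early neuron, 0.0047 for GABA, 1.27e-09 for hypoxia and glycolysis, 3.05e-06 for endoderm and epithelium, 3.09e-05 for mesenchyme, 3.50e-06 for mitochondrially encoded, 4.03e-04 for stress, 0.0168 for migration, 0.016 for cell cycle, 0.00856 for astrocyte, 0.00127 for matrix and 0.0106 for endothelium and microglia genes. With an estimated correlation, the calls that hold are pluripotency (adjusted p = 0.0384), early neuron (0.00933), hypoxia and glycolysis (0.00112) and stress (0.0347). With week 8 in place of week 4 those of pluripotency and early neuron genes were lost (adjusted p = 0.0662 and 0.0662 with an estimated correlation). The adjusted p with an estimated correlation was 0.091 for ventral telencephalic factors, 0.175 for GABA, 0.0503 for endoderm and epithelium, 0.0503 for mesenchyme, 0.0649 for mitochondrially encoded, 0.483 for migration, 0.0649 for cell cycle, 0.091 for astrocyte, 0.296 for matrix and 0.091 for endothelium and microglia genes. It was 0.568 for MGE precursor, 0.417 for radial glia and 0.569 for synapse genes, which missed the preset test too (adjusted p = 0.168, 0.0562 and 0.168). Counts adjusted over the list alone were the same for every list in this comparison.

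Of 19098 genes tested, 11668 were higher and 4244 lower at week 4, 6036 and 1823 of them at least 2-fold. This split rests on the scaling of TPM. With median-of-ratios scaling 7683 genes were higher and 7724 lower, and with quantile normalization 7888 and 7167. The week 4 libraries also stand apart from the rest of the LHX6 line: 45 genes differed over 8-fold on the log2(TPM + 1) scale from each of the stem cell, week 6, week 7 and week 8 groups. CHCHD2 (ENSG00000106153, chromosome 7, 56101569 to 56106576), for instance, was at 5.70 ± 2.20 TPM at week 4 and between 369 and 513 in the other groups of the line. With week 6 in place of week 4, 11894 genes were higher and 4138 lower than in stem cells, and 17 of 17 pluripotency genes fell. Replacing week 4 by week 6 or 8 against stem cells, here and above, carries a doubt of its own. Against stem cells, 7 chromosomes chosen on week 6 lay 0.317 above the other autosomes at week 6 and 0.268 at week 8. At week 4 the gap was 0.048. This shift is described under the other observations.

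**Figure D2:**
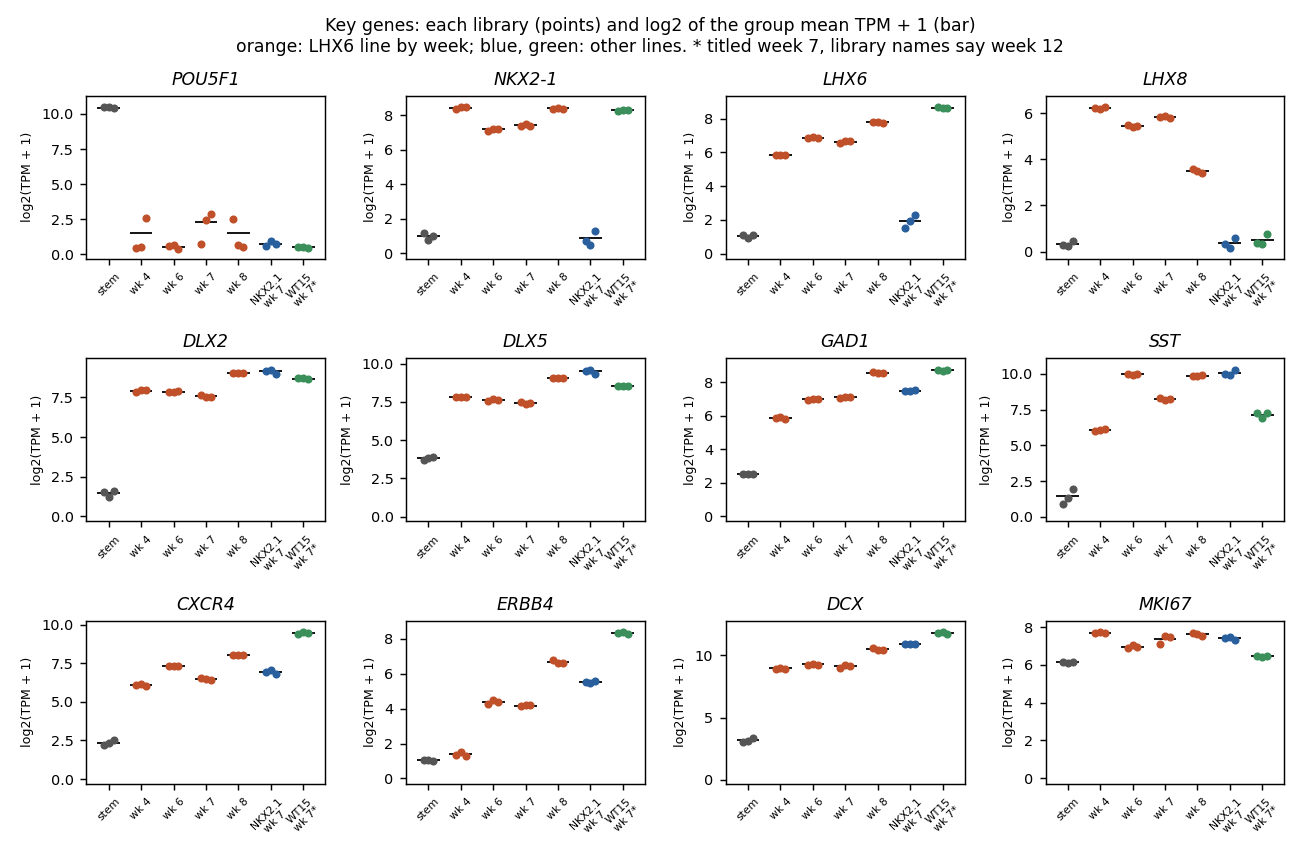
TPM of 12 key genes in each library (points; log2(TPM + 1) axis) with the group mean (bar) for the 7 groups. POU5F1 is high in stem cells alone, and NKX2-1 and LHX6 average at most 2.85 TPM in stem cells and in the NKX2.1 line.

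The week 6 libraries had less of cell cycle transcripts than those of week 4. Because of the doubt about the week 4 libraries, a change over time cannot be told apart from a difference in cells. Mesenchyme and pericyte genes rose in 11 of 13 cases (1 fell), a call lost with an estimated correlation (adjusted p = 0.103), COL3A1 by 3.77 and LUM from 0.780 ± 0.171 to 33.9 ± 0.977 TPM. NKX2-2 (ENSG00000125820, chromosome 20, 21511010 to 21514026), a ventral midline factor, rose from 2.04 ± 0.589 to 195 ± 5.94 TPM (log2 change 6.03 ± 0.14 (SE), adjusted p = 5.42e-13), FOXA1 from 0.985 ± 0.0896 to 95.7 ± 1.42, FOXA2 by 5.28 and the morphogen SHH (ENSG00000164690, chromosome 7, 155799986 to 155812273) by 3.42. The list of diencephalon, midbrain and hindbrain genes, which holds FOXA1 and FOXA2, was not called, with 5 of 10 risen and 2 fallen (camera adjusted p = 0.283). Cell cycle genes fell in 21 of 22 cases, TOP2A by a log2 change of -1.26 and MKI67 from 206 ± 4.45 to 124 ± 6.11 TPM. Ventral telencephalic progenitor factors fell in 12 of 15 cases (1 rose), with NKX2-1 at 143 ± 6.03 TPM. Mitochondrially encoded genes fell in 11 of 11 cases, against 5 that fell and 1 that rose with quantile normalization (camera adjusted p = 0.219).

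MGE-derived interneuron precursor genes rose in 12 of 16 cases (4 fell), ERBB4 from 1.61 ± 0.245 to 20.1 ± 1.49 TPM and LHX6 to 116 ± 2.12. SST went from 66.3 ± 2.18 to 1003 ± 13.5 and GAD1 from 57.4 ± 1.63 to 126 ± 2.27. Synapse and excitability genes rose in 22 of 26 cases (3 fell), such as GRIA4 (1.43). Astrocyte genes rose in 9 of 10, such as CLU (1.87) and SPARCL1 (3.86). Levels within the astrocyte list differed widely at week 6. CLU was at 200 and SPARCL1 at 68.2 TPM, but GFAP at 2.42, AQP4 at 4.53 and S100B at 5.20. Matrix proteases, inhibitors and integrins rose in 18 of 27 cases (6 fell), TIMP3 by 2.07. Of 21 receptors for glioma-secreted factors 8 rose and 9 fell, or 8 and 10 adjusted over the list alone (camera adjusted p = 0.506), with CXCR4 at 1.23 and CD44 at 3.44. The list median was -0.042 and the mean 0.21, here not taken relative to all genes. CHCHD2 (6.03) completes the 3 largest rises, and the largest falls were those of PSPHP1 (-6.19), LRRC61 (-5.37) and CAPN6 (-5.35). CHCHD2, PSPHP1 and LRRC61 are among the 45 genes that set week 4 apart, and the level of PSPHP1 is uncertain because a pseudogene can share reads with its parent gene. Gene levels at week 6 also differed from week 4 by chromosome, in protein-coding genes of 5 TPM or more after correction for GC content and length. Over genes past the middle gene by position, the median change was 0.18 for chromosomes 1, 3, 6, 7, 9, 12 and 20. For the other 15 autosomes it was -0.11. The first 7 were chosen on genes before the middle gene, for a median change over 0.1 at week 6 against stem cells. The week 6 libraries thus entered both the choice and the reading. Of the genes named for this comparison, NKX2-2, FOXA2, SHH, LUM, LHX6, SST, CHCHD2, PSPHP1 and LRRC61 lie on these 7 chromosomes.

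Of the list calls, that of the cell cycle held with both forms of camera (adjusted p = 2.46e-12 with the preset and 3.97e-04 with an estimated correlation). The preset gave 4.74e-05 for mesenchyme, 1.71e-05 for synapse, 8.96e-04 for astrocyte, 9.01e-06 for ventral telencephalic, 0.00431 for MGE precursor, 0.0226 for matrix and 1.71e-05 for mitochondrially encoded genes. Under camera with an estimated correlation the adjusted p was 0.103, 0.18, 0.103, 0.158, 0.283, 0.454 and 0.155 in the same order. Apart from the receptor list, counts adjusted over the list alone equalled these. Over all genes 7096 were higher and 5169 lower at week 6, against 6063 and 6155 with median-of-ratios scaling and 5844 and 6454 with quantile normalization.

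Week 7 cultures had more cell cycle and mitochondrial transcripts than week 6 cultures and less of MGE-derived interneuron precursor genes, the last a call lost with an estimated correlation (adjusted p = 0.292). EGR1 rose to 116 ± 6.39 TPM (log2 change 2.89 ± 0.055 (SE), adjusted p = 3.13e-12) and FOS by 1.95, but the stress and immediate early list that holds them went both ways, with 4 of 14 risen and 5 fallen, or 5 and 7 adjusted over the list alone (camera adjusted p = 0.801). Cell cycle genes rose in 17 of 22 cases (19 adjusted over the list alone), CENPF by 1.32, and mitochondrially encoded genes in 11 of 11. The camera adjusted p was 1.47e-10 for each, and both calls held with an estimated correlation (adjusted p = 8.80e-04 and 0.0421). Most cell cycle genes rose far less than CENPF. Their median log2 change was 0.159 with median-of-ratios scaling and 0.225 with quantile normalization. NPY, a neuropeptide of interneurons, fell from 13.2 ± 1.42 to 1.13 ± 0.634 TPM, SST from 1003 ± 13.5 to 303 ± 16.0 and CXCR4 by a log2 change of -0.83. MGE-derived interneuron precursor genes fell in 11 of 16 cases (list median -0.20 relative to all genes), LHX6 at 98.3 ± 5.35 TPM (camera adjusted p = 0.00127 with the preset correlation). The remaining large changes were rises of RNU7-71P (2.71) and RNU6-26P (2.30), copies of small nuclear RNA genes whose levels are uncertain, and falls of CXCL2 (-2.21) and UBD (-2.08). Without replicate 2 of week 6 the rise of RNU6-26P was 1.71 with an adjusted p of 0.0577. Of all genes 3002 were higher and 3427 lower at week 7, 70 and 44 of them by 2-fold or more, and with mitochondrial genes left out and TPM rescaled the balance turned to 3637 and 2328.

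From week 7 to week 8 MGE-derived interneuron precursor genes rose while diencephalon to hindbrain, mesenchymal and SHH and WNT readout genes fell. LHX6 rose from 98.3 ± 5.35 to 217 ± 5.41 TPM (log2 change 1.13 ± 0.051 (SE), adjusted p = 3.19e-10), DLX2 to 534 ± 4.44, DLX5 to 546 ± 1.01, GAD1 to 383 ± 6.98 and ERBB4 from 17.1 ± 0.590 to 102 ± 6.99. MGE-derived interneuron precursor genes rose in 14 of 16 cases (1 fell), and GABA genes in 4 of 5. CXCR4 rose to 261 ± 4.75, ACKR3 to 147 ± 4.08 and DCX from 556 ± 47.6 to 1422 ± 67.2. NKX2-1 went to 334 ± 5.66 TPM, while LHX8, a factor of cholinergic neurons, fell from 55.4 ± 1.85 to 10.2 ± 0.737.

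SHH fell from 313 ± 4.82 to 15.1 ± 0.698 TPM. Of the SHH and WNT pathway readouts, a list that holds SHH itself, 10 of 10 fell, PTCH1 by a log2 change of -2.03. NKX2-2 fell from 195 ± 3.67 to 2.32 ± 0.378 TPM, and FOXA1 and FOXA2 changed by -4.23 and -3.99 in the list of diencephalon, midbrain and hindbrain genes, of which 8 of 10 fell. Mesenchyme and pericyte genes fell in 11 of 13 cases (1 rose), such as COL3A1 (-2.48), stress and immediate early genes in 11 of 14, cholinergic and striatal projection neuron genes in 7 of 9 (1 rose), such as ISL1 (-2.77), and oligodendrocyte lineage genes in 8 of 9 (1 rose). Matrix genes fell in 23 of 27 cases (2 rose) and receptors for glioma-secreted factors in 14 of 21 (4 rose), among them NRP1 (-2.47). The largest rises were those of GPD1 (3.53), BRINP2 (3.48) and PDZRN4 (3.47), and next to NKX2-2 the largest falls were those of EFCC1 (-5.06) and CTGF (-4.89).

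With an estimated correlation the camera adjusted p was 0.0289 for MGE precursor, 0.0226 for SHH and WNT, 0.0226 for diencephalon to hindbrain, 0.0344 for mesenchyme, 0.0226 for stress, 0.0289 for cholinergic and striatal and 0.0289 for oligodendrocyte genes. The calls for matrix, receptor and GABA genes (preset adjusted p = 1.06e-05, 0.0115 and 6.86e-04) were lost, with an adjusted p of 0.151, 0.285 and 0.137 with an estimated correlation. Over all genes 5801 were higher and 5832 lower at week 8, 627 and 1419 of them at least 2-fold, against 6065 and 5524 with median-of-ratios scaling and 6339 and 5452 with quantile normalization. Counts adjusted over the list alone were the same for the lists named here.

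Over the whole span from week 4 to week 8, 16 of 16 MGE-derived interneuron precursor genes rose, ERBB4 by 5.31, MAF by 3.27 and LHX6 from 56.0 ± 0.404 to 217 ± 5.41 TPM (log2 change 1.93 ± 0.051 (SE), adjusted p = 1.23e-12). GAD1 rose by 2.72, GAD2 by 1.46, SST by 3.81 and CXCR4 by 1.94. From week 6 to week 8 the log2 change of SST was -0.091 (adjusted p = 0.708). Of 26 synapse and excitability genes 19 rose and 5 fell, GRIA4 rising by 3.57, and of 10 interneuron subtype peptides and calcium-binding proteins 6 rose and 1 fell, against 4 risen and 3 fallen from week 6 (camera adjusted p = 0.689). Of 22 cell cycle genes 17 fell and 0 rose, but with week 6 in place of week 4, 14 rose and 6 fell (camera adjusted p = 0.0267, and 0.112 with an estimated correlation). Astrocyte genes rose in 8 of 10 cases and fell in 2 (camera adjusted p = 0.0857), against 3 risen and 6 fallen from week 6. SHH and WNT pathway readouts fell in 7 of 10 cases and rose in 1 (camera adjusted p = 0.00357, and 0.101 with an estimated correlation). Cortical glutamatergic genes fell in 6 of 7 cases, EMX2 by a log2 change of -4.13, and cholinergic and striatal projection neuron genes in 7 of 9, EBF1 by -4.22. EBF1 is among the 45 genes that set week 4 apart. From week 6 to week 8 its log2 change was -0.92, and that of EMX2 -1.06. NKX2-1 was at 339 ± 13.7 TPM at week 4 and 334 ± 5.66 at week 8.

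The largest rises were those of CHCHD2 (6.32), NXPH1 (6.11), the interferon-induced gene IFI44 (6.08), the pseudogene COX20P1 (5.35) and ERBB4, and the largest falls those of CAPN6 (-6.08), PSPHP1 (-5.92), DIO3 (-5.78), the cyclin gene CCND1 (-5.61) and MAGEA4 (-5.56). CHCHD2, COX20P1 and PSPHP1 are among the 45 genes that set week 4 apart. Relative to week 4, genes past the middle gene of the 7 chromosomes named for week 6 lay 0.263 above those of the other autosomes at week 8. Under camera with an estimated correlation the adjusted p was 0.036 for MGE precursor, 0.00644 for cell cycle, 0.0386 for cortical glutamatergic and 0.036 for cholinergic and striatal genes, and 0.307 for synapse genes, whose preset value was 0.00587. Of all genes 7576 were higher and 5736 lower at week 8. With week 6 in place of week 4, 6087 were higher and 6139 lower, 15 of 16 MGE precursor genes rose, and synapse genes turned to 9 risen and 13 fallen. The adjusted p with an estimated correlation was then 0.072 for MGE precursor, 0.326 for cortical glutamatergic and 0.0785 for cholinergic and striatal genes, so that none of these calls held. Counts adjusted over the list alone were the same for the lists named here.

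**Figure D3:**
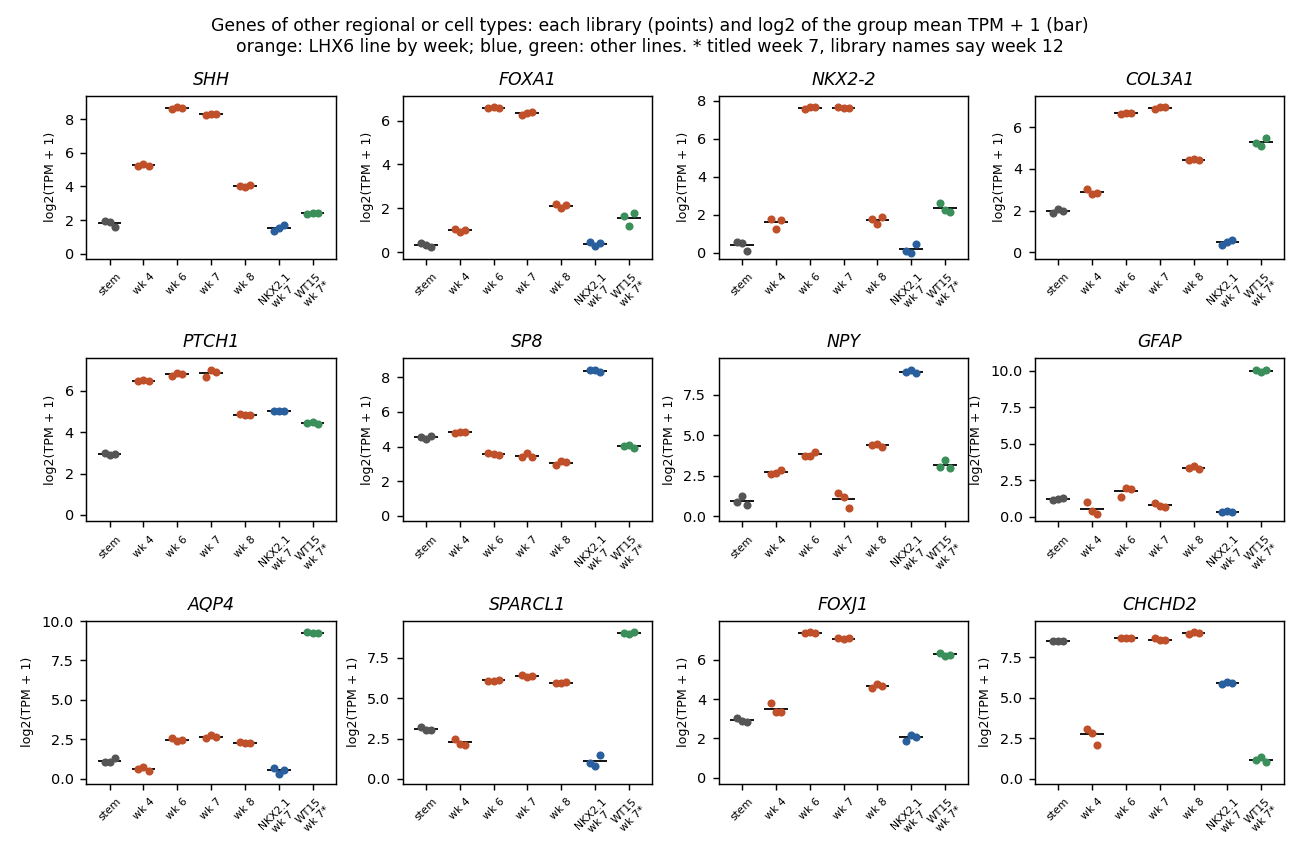
TPM of 12 genes of other regional or cell types in each library (points; log2(TPM + 1) axis) with the group mean (bar) for the 7 groups. SHH, FOXA1, NKX2-2 and COL3A1 are highest at weeks 6 and 7 of the LHX6 line, SP8 and NPY in the NKX2.1 line, and GFAP and AQP4 in the WT15 line.

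Line and batch cannot be told apart in the next comparison, of the NKX2.1 with the LHX6 line at week 7. The NKX2.1 line had little of the factors that mark the medial ganglionic eminence: NKX2-1 was at 0.830 ± 0.546 TPM against 168 ± 6.62 in the LHX6 line (log2 change -6.57 ± 0.17 (SE), adjusted p = 4.70e-09), LHX6 at 2.85 ± 1.00 against 98.3 ± 5.35 and LHX8 at 0.283 ± 0.202 against 55.4 ± 1.85. This line is named for a reporter of NKX2-1, and the labels used here do not say whether cells were sorted or the differentiation differed, so it is uncertain what these libraries represent, mislabelling included, in every comparison with the libraries labelled as the NKX2.1 line. Higher in it were DLX2 at 568 ± 49.2, DLX5 at 722 ± 68.9, GAD2 at 259.6 ± 2.64 and SST at 1081 ± 148 TPM. Other weeks of the LHX6 line came near some of these levels, with SST at 1003 TPM at week 6 and 941 at week 8, and DLX2 at 534 at week 8. At week 8 DLX5 (546) and GAD2 (176) stayed below the NKX2.1 line. Genes of the caudal and lateral ganglionic eminence were higher in 6 of 10 cases (3 lower): SP8 at 335 ± 12.7 against 10.2 ± 0.974, MEIS2 by 2.92 and PAX6 by 4.06. Interneuron peptides and calcium-binding proteins were higher in 9 of 12 cases (1 lower), with NPY, first among the largest rises, at 491 ± 35.4 TPM, CALB2 higher by 5.34 and RELN at 125 ± 14.7 against 5.43 ± 1.05. Of 16 MGE-derived interneuron precursor genes 8 were higher and 7 lower, with a camera adjusted p of 0.99. The list median was 0.10 and the mean -0.054, here not taken relative to all genes, and the median was -0.055 with median-of-ratios scaling. Early neuron genes were higher in 12 of 13 cases and synapse genes in 21 of 26 (3 lower).

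Lower in the NKX2.1 line were 11 of 12 (1 higher) mesenchyme and pericyte genes (COL3A1 -6.45), 7 of 8 (1 higher) diencephalon, midbrain and hindbrain genes (FOXA1 -5.97), 8 of 9 SHH and WNT readouts (SHH -6.78) and 8 of 10 (1 higher) astrocyte genes (SPARCL1 -5.27). The LHX6 line itself had less of many of these by week 8, with COL3A1 at 20.8 TPM, FOXA1 at 3.35 and SHH at 15.1. SPARCL1 stayed at 61.8. From week 6 to week 8, 11 of 13 mesenchyme genes (1 rose) and 10 of 10 SHH and WNT readouts fell in that line. Across genes the NKX2.1 line correlated at 0.905 with week 8 of the LHX6 line and at 0.864 with week 7. NKX2-2 (-7.42) and the pseudogene RPSAP47 (-6.50) also fell among the largest 5, and the remaining largest rises were PSPHP1 (6.19), AMBN (5.85), LRRC61 (5.54) and TUSC1 (5.47). The preset camera adjusted p was 6.06e-06 for mesenchyme, 5.61e-04 for diencephalon to hindbrain, 1.27e-04 for SHH and WNT, 0.00169 for astrocyte, 0.00169 for early neuron, 0.00169 for synapse, 0.0103 for interneuron peptides and 0.138 for CGE and LGE genes. With an estimated correlation no list kept its call, and the adjusted p was 0.107 for mesenchyme, diencephalon to hindbrain, SHH and WNT, astrocyte, early neuron and interneuron peptide genes, 0.446 for synapse and 0.527 for CGE and LGE genes. Counts adjusted over the list alone were the same for these lists. Of 18882 genes tested 8196 were higher and 5292 lower. The split was 6675 and 6674 with median-of-ratios scaling and 6537 and 6759 with quantile normalization. Over genes past the middle gene, the median change of the 7 chromosomes named for week 6 minus that of the other autosomes was -0.289. This gap is for the NKX2.1 line relative to the LHX6 line.

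The WT15 line, whose libraries are titled week 7 but named week 12, had more astrocyte transcripts than the LHX6 line, and line and batch cannot be told apart here either. Astrocyte genes were higher in 9 of 10 cases (1 lower), a call lost with an estimated correlation (adjusted p = 0.116), as were the other list calls of this comparison. GFAP (ENSG00000131095, chromosome 17, 44903161 to 44916937), the astrocyte filament gene, was at 1024 ± 66.1 TPM against 0.745 ± 0.182 (log2 change 9.20 ± 0.084 (SE), adjusted p = 2.26e-11), the water channel gene AQP4 at 613 ± 6.99 against 5.36 ± 0.431 and NFIX, a factor of glial maturation, at 322 ± 14.2 against 2.47 ± 0.210. MGE-derived precursor genes were higher as well, in 15 of 16 cases (1 lower) and GABA genes in 5 of 5: LHX6 was at 398 ± 7.82 TPM, ERBB4 at 323 ± 8.00, CXCR4 at 695 ± 25.3, DCX at 3519 ± 121 and NKX2-1 at 308 ± 1.85. LHX8 was at 0.421 ± 0.252. SST was lower, at 142 ± 19.2 against 303 ± 16.0 TPM, and of 12 interneuron peptides and calcium-binding proteins 7 were higher and 4 lower (camera adjusted p = 0.637). Of 22 cell cycle genes 22 were lower, MKI67 at 86.9 ± 1.17 against 166 ± 26.5.

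Diencephalon, midbrain and hindbrain genes were lower in 8 of 8 cases, SHH and WNT readouts in 8 of 9 (1 higher), SHH by -5.90, endoderm and epithelium genes in 5 of 5 and stress genes in 10 of 14. In the LHX6 line itself 7 of 10 diencephalon to hindbrain genes and 10 of 10 SHH and WNT readouts fell from week 6 to week 8. SHH was at 15.1 TPM at week 8 of that line. Across genes the WT15 line correlated at 0.917 with week 8 of the LHX6 line and at 0.868 with week 7. Other large rises were GPD1 (7.06) and ANGPT2 (6.74), and the other large falls MEST (-7.56), CHCHD2 (-7.43), COL2A1 (-7.38) and RPSAP47 (-6.50). The preset camera adjusted p was 7.34e-12 for cell cycle, 2.33e-05 for MGE precursor, 3.76e-05 for diencephalon to hindbrain, 8.55e-04 for astrocyte, 8.55e-04 for SHH and WNT, 8.55e-04 for GABA, 8.55e-04 for stress and 0.00239 for endoderm genes. Under camera with an estimated correlation no list kept its call, and the adjusted p was 0.126, 0.0647, 0.0647, 0.116, 0.126, 0.156, 0.0647 and 0.0893 in the same order. Counts adjusted over the list alone were the same for these lists. Over genes past the middle gene, the median change of the 7 chromosomes named for week 6 minus that of the other autosomes was -0.262. This gap is for the WT15 line relative to the LHX6 line. Of all genes 7635 were higher and 5591 lower in the WT15 line, against 6502 and 6643 with median-of-ratios scaling and 6393 and 6680 with quantile normalization.

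The WT15 and NKX2.1 lines share batch 2, so the labelled batch does not separate them. The doubt about the libraries labelled as the NKX2.1 line applies here too. The WT15 line had more astrocyte, MGE and mesenchymal transcripts, and the NKX2.1 line more cell cycle transcripts and more of interneuron types of the caudal and lateral eminence. None of these list calls held with an estimated correlation (adjusted p = 0.0775 for astrocyte, 0.108 for MGE precursor, 0.108 for mesenchyme, 0.155 for cell cycle and 0.322 for CGE and LGE genes). Astrocyte genes were higher in the WT15 line in 9 of 10 cases (1 lower), with GFAP at 0.275 ± 0.0179 TPM in the NKX2.1 line (log2 change 9.65 ± 0.084 (SE), adjusted p = 2.91e-11), AQP4 higher by 8.73 and SPARCL1 by 7.93. NKX2-1 (log2 change 7.44 ± 0.17 (SE), adjusted p = 3.18e-09) and LHX6 (6.73) were higher, as were ERBB4 (2.81), CXCR4 (2.50) and ACKR3 (2.50). CRABP1, a retinoid-binding protein gene, was at 2548 ± 36.7 against 3.02 ± 1.61 TPM. MGE-derived precursor genes were higher in 11 of 16 cases (5 lower), mesenchyme and pericyte genes in 9 of 12, choroid plexus and ependyma genes in 6 of 7, such as FOXJ1 (4.23), and oligodendrocyte lineage genes in 7 of 9, such as MBP (3.53).

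Lower in the WT15 line were 22 of 22 cell cycle genes, 7 of 10 (3 higher) CGE and LGE interneuron genes (SP8 -4.37), 7 of 12 (4 higher) interneuron peptides (RELN -6.14, NPY -5.79, SST -2.92) and 10 of 14 stress genes. AMBN (-6.04), the pseudogene RPL18P11 (-5.48) and FOXP4 (-5.20) were the other largest falls. The preset camera adjusted p was 3.79e-07 for astrocyte, 0.0024 for MGE precursor, 9.40e-05 for mesenchyme, 1.30e-04 for choroid plexus, 3.23e-04 for oligodendrocyte, 1.54e-10 for cell cycle, 0.00664 for CGE and LGE, 0.198 for interneuron peptides and 3.99e-04 for stress genes. With an estimated correlation the adjusted p was 0.0804 for choroid plexus, 0.108 for oligodendrocyte, 0.325 for interneuron peptides and 0.0775 for stress genes. Of all genes 4895 were higher and 5673 lower in the WT15 line, a balance that turned to 5416 and 5189 with median-of-ratios scaling and 5616 and 5152 with quantile normalization. Counts adjusted over the list alone were the same for these lists. Line and any difference in time in culture cannot be told apart here.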

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

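The versions without mitochondrial genes, with protein-coding genes only, and with week 4 replaced or left out were tests chosen only after the results were seen. TPM keeps no read depth, so the counting error of low genes is unknown. Each of the 16 counts of higher or lower genes stayed within 1.5 times its value with a pseudocount of 0.1 and without the filter. So it did in fits of fewer or more libraries and in the versions chosen later. A similar count can hold other genes. For week 8 with week 6 in place of week 4, 4257 of the 7576 higher and 3599 of the 5736 lower genes were called again. Against stem cells, 10291 of the 11668 genes higher at week 4 were also higher at week 6. With median-of-ratios scaling the genes higher at week 4 than in stem cells numbered 7683 and the lower ones 7724, and with quantile normalization the lower ones numbered 7167. These scalings remove the shift of the median gene by construction. The test against a log2 change of 1 asks for a larger change by construction, and gave 4493 higher and 1490 lower genes for week 4 against stem cells, 861 and 328 for week 6 against week 4, 4 and 5 for week 7 against week 6, 259 and 937 for week 8 against week 7, and 636 and 801 for week 8 against week 4. For the lines it gave 1361 and 951 for NKX2.1 against LHX6, 1214 and 916 for WT15 against LHX6, and 695 and 723 for WT15 against NKX2.1. Without one replicate the count for week 7 against week 6 ranged from 2567 to 3203 higher and 2776 to 3383 lower, and that for week 4 against stem cells from 11325 to 11401 and 3810 to 4147. Replicate numbers shared between groups did not pair the libraries, since the correlations of deviations between same-numbered libraries were 0.053 or less. With the replicate number as a block, 11634 genes were higher and 4242 lower at week 4 than in stem cells, and no count moved by over 1.5 times. Among single genes, ERBB4 at week 4 against stem cells went from a log2 change of 0.34 to -0.030 with median-of-ratios scaling and -0.30 with quantile normalization. Its 0.34 lay below the shift of the median gene (0.55) that both scalings remove, so a drop follows from the scaling itself. Fry gave the opposite direction to camera for receptors for glioma-secreted factors at week 6 against week 4 (adjusted p = 1.14e-05) and in the WT15 against the LHX6 line (0.0512), and for MGE-derived interneuron precursors in the NKX2.1 against the LHX6 line (5.43e-07), lists whose members went both ways; fry tests a list alone, not against other genes. With quantile normalization camera also turned the direction of the latter list (adjusted p = 0.736), which it had not called. Of 82 list results in the text, 48 calls were lost with an estimated correlation in place of the preset one. The other 34 include lists that the preset test had not called either. The lost calls are therefore a larger share of the calls made than of the 82.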

Other observations

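The explanations below were all tested only after the patterns had been seen, and so were the splits of the libraries.

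Receptors for factors that gliomas secrete gave no list call that held with an estimated correlation between the lines at week 7. In the NKX2.1 line 10 of 19 were lower and 7 higher than in the LHX6 line (camera adjusted p = 0.0338, and 0.401 with an estimated correlation; 12 lower and 3 higher with quantile normalization), the lower ones including NRP1 (-1.90), PDGFRB (-2.62), CD44 (-2.55) and ACKR3 (-1.57). In the WT15 line 8 were higher and 8 lower than in the LHX6 line (adjusted p = 0.637). In the same line 10 were higher and 7 lower than in the NKX2.1 line (adjusted p = 0.0775), with CXCR4 at 695 ± 25.3 against 123 ± 12.8 TPM, EGFR at 59.6 ± 3.83 against 8.66 ± 0.371 and CD44 at 11.9 ± 0.472 against 1.30 ± 0.0984. Matrix proteases, inhibitors and integrins were higher in 15 of 26 cases and lower in 7 (adjusted p = 0.017, and 0.4 with an estimated correlation), MMP2 by 2.51 and TIMP3 by 2.16.

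Members of the migration and guidance list went both ways over the LHX6 time course: EPHA5 rose by 3.22 and ROBO2 by 1.84 from week 4 to week 8, while NRP1 fell by a log2 change of -2.19 and EPHB3 by -1.44, and 11 of 21 migration genes rose and 9 fell (adjusted p = 0.544). The choroid plexus and ependyma list was not called at week 6 against week 4 (adjusted p = 0.183), with 5 of 8 risen and 1 fallen: FOXJ1, a factor of motile cilia, was at 165 ± 2.34 against 10.4 ± 2.21 TPM and PIFO rose by 4.02, while OTX2 fell by a log2 change of -2.36.

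The week 4 libraries stood apart from the other LHX6 line groups in 45 genes, 13 lower and 32 higher, against 537 such genes for stem cells, 9 for week 8 and 0 each for weeks 6 and 7, which lie too close together for either to stand apart easily. For 34 of the 45, both other lines at week 7 lay on the side of week 4, which argues against a passing stage at week 4 as the cause for these, while for the remaining 11 a stage cannot be told apart from other causes because one or neither line shared the level. Among 44 genes that part the other lines from the LHX6 line and were chosen without week 4, week 4 lay with the other lines for 39. The count was 0 of 3 when week 6 or week 7 was left out instead and 4 of 10 for week 8. These are no control for the 39, because such selections exclude genes for which week 4 lay with the other lines. Weeks 6 and 7 are also so close that keeping either largely fixes where the other falls. A candidate explanation is that the week 4 libraries hold cells of another line or clone, which these data alone cannot settle.

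From week 6 on, the LHX6 line differed from week 4 by whole chromosomes. Over 22 autosomes the median changes of genes before and after each chromosome's middle gene correlated at 0.906 for week 6 against week 4 after correction for GC content and transcript length (1e-05 by permutation, one-sided, the smallest p the permutations can give), which argues against those biases as the whole cause. A set of 7 chromosomes, chosen on the genes before the middle in week 6 and stem cells, stood wholly apart on the genes after it in the WT15 line against week 8, by -0.217, and in week 8 against stem cells 5 of the 7 lay above every other autosome, but the set differed by 0.048 in week 4 against stem cells and 0.014 between the other lines. This is consistent with a difference in chromosome copy number in weeks 6 to 8, as a hypothesis. No DNA was measured, and 1 extra copy of 2 would give 0.585, above these gaps.

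Astrocyte genes were higher in the WT15 line than in the NKX2.1 line of the same labelled batch for 9 of 10, which argues against that batch as the cause. Longer culture, as the library names of week 12 would have it, may account for them, and 22 of 22 cell cycle genes were lower, but culture time cannot be told apart from the line because both lines were sampled once. The difference between the lines themselves stays open as untested.

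Each comparison has 3 libraries against 3, and the 10 splits of 6 libraries are too few for a share under 0.05. The real split gave 15912 changed genes for week 4 against stem cells (1 of 10 splits as large, highest other 0), 12265 for week 6 against week 4 (highest other 1), 6429 for week 7 against week 6 (highest other 2), 11633 for week 8 against week 7 (highest other 3) and 13312 for week 8 against week 4 (highest other 0). For the lines it gave 13488 for NKX2.1 against LHX6, 13226 for WT15 against LHX6 and 10568 for WT15 against NKX2.1, each with a highest other of 0.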
